A study of Mus musculus with 28 samples.

How the data were processed

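RNA was measured in synaptosomes, pinched-off nerve terminals with attached postsynaptic membrane, from mouse brain. Per the labels' protocols, a crude pellet was taken up in 10 µL of PBS and sorted particles in 10 µL of TCEP, a reducing agent, and RNA was amplified to cDNA with the Repli-g WTA single cell kit. Per the same labels, the mRNA libraries were built on the 10x Genomics platform and sequenced in paired-end mode on an Illumina HiSeq. The series has 28 libraries. Of these, 20 belong to the SynSURF preparation (10 crude and 10 sorted) and 6 to a sucrose gradient preparation (3 crude and 3 sorted). The other 2, total RNA of sorted synaptosomes, are not analysed here. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

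The authors deposited values that are estimated counts of reads per gene symbol for both preparations, in separate tables of 25239 genes (SynSURF) and 24443 genes (sucrose). The submitters' processing notes name fastp, HISAT2, GRCm38 and GRCm39 with no role, order or version. The counting tool, the annotation, the strand setting and the build behind each table are not given in the sources used here. Most counts were whole, and 7278 values in the SynSURF table and 4660 in the sucrose table were not, so all were rounded to whole numbers before any test. No gene with an mt- symbol was in the count tables used, so the planned share, gene list and alternative setting for mitochondrially encoded RNA are not analysed here, and neither is mt-Co1. Where reads come from genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, the split between copies depends on the authors' counting. Per the file headers, the sucrose workbook also gives the authors' own comparison as a fold and a second value named PPEE, whose meaning the header does not spell out. That table names the non-crude libraries "4", and no label uses this name. The 44 other columns of per-sample values were not used here.

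Groups were taken from the sample titles. The sorted and crude libraries of each preparation were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors, the default expression filter (filterByExpr), group as the only term, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. CPM are relative to the TMM-scaled library total, so a gene's CPM can exceed its plain share of counts. The difference between the preparations was the contrast of both sorted-minus-crude effects in one 4-group edgeR fit over the 23466 gene symbols in both tables. The 23 gene lists were fixed before the data were examined. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), adjusted over the lists. Estimated correlation and fry were alternatives. Shares of counts and genes detected were compared with 2-sided permutation tests of the difference of means, with 100000 resamples for 10 against 10 libraries (smallest possible p = 1e-05), and exact for 3 against 3 (smallest possible p = 0.1). For genes detected, libraries were thinned once, with a fixed seed, to the shallowest total of the preparation, 76520 counts for SynSURF and 1844679 for sucrose.

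Genes named in the text were chosen by a rule fixed before the data were examined. Among genes past the threshold with a mean CPM of at least 10, the 6 highest and the 6 lowest fitted log2 fold changes of each comparison were taken, leaving out predicted-gene and clone names. Up to 3 members with the highest mean CPM were taken from each list that passed its test, plus a fixed panel of neuronal, glial and control genes. Some genes that this rule takes are not reported here. Beyond this rule, and after their values were seen, the 10 genes whose sorted libraries all lay above every crude library were named, and so were the 2 most abundant called members of each synaptic or cell type list not already named. Gene positions come from GENCODE M21 on GRCm38 and were not used in any test. Transcript length is the longest annotated transcript, found for 98.9% of the tested SynSURF genes.

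Alternatives set before the data were examined were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma voom with sample weights, no filter, a minimum of 5 CPM, a replicate block, a minimum log2 fold change of 1, and leaving out each library. Leaving out libraries with few counts, at a minimum set in advance, removed none of the sucrose libraries and would have kept only 1 SynSURF sorted library, so it was not run. Alternatives added after seeing the data were library totals with no TMM factors, SynSURF sorted replicate 4 left out, sorted replicates 1 and 4 left out, crude libraries thinned to the totals of the sorted libraries, Rn45s removed, a block of the sucrose pairs alone in the fit of the difference, and the Rn45s share as a measure. Replicate numbers are shared between crude and sorted libraries. In the sucrose set the deviations of same-numbered libraries from their group means correlated at 0.336, 0.473 and 0.323, all over the minimum of 0.1, so the numbers were taken to pair those libraries, from the data, since the labels do not state a pairing.

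The SynSURF crude libraries held 1035423 to 8897238 counts and the sorted libraries 76520 to 1812759. Where a gene had no count in a group, its fold set the pooled count rate of the other group against a floor of 3 counts over the whole group. That pooled rate gives deep libraries more weight, so such a fold can differ from one taken from the mean CPM. Intervals for the share of one library are 95% Wilson intervals. Intervals and floors cover counting error only, since amplified reads are not independent molecules. TMM factors were 1.20 to 1.62 in the SynSURF crude and 0.304 to 0.953 in the sorted libraries.

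The tests were checked on simulated data with negative binomial counts, each gene's mean in the crude libraries, each group's own spread and the TMM-scaled library totals. For the SynSURF sorted libraries these scaled totals lay below the real ones, so the simulated gap in depth was wider. Earlier simulations with smaller folds, another baseline and a pooled spread recovered few changes, and folds of 8, 32 and 128 were then used. In the SynSURF simulation of 6598 genes, edgeR recovered 45.5%, 88.9% and 100% of genes raised by these folds, and 61.3%, 76.5% and 68.6% of genes lowered by them. It called 2 of 6398 unchanged genes higher and 256 lower. In the sucrose simulation of 10589 genes, the same test recovered 91.7%, 100% and 100% of raised and 71.9%, 73.5% and 87.2% of lowered genes, and called 3 of 10389 unchanged genes higher and 2 lower. For the difference between preparations, over 10713 genes, 0%, 0% and 7.7% of raised and 17.6%, 34.6% and 58.3% of lowered genes were recovered, and of 10513 unchanged genes 0 were called higher and 59 lower. In a simulation that raised the astrocyte list 2-fold, camera called that list in both preparations and no other list. Genes were drawn independently of each other there, so it could not check false list calls where members vary together.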

Results

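Poly(A) RNA of mouse brain synaptosomes was profiled before sorting (crude) and after sorting in 2 preparations. The SynSURF preparation, which sorts synaptosomes held by a reversible fixative, had 10 crude and 10 sorted libraries. The sucrose gradient preparation had 3 crude and 3 sorted libraries. The values are the authors' deposited estimated counts per gene, rounded to whole numbers. Levels below are CPM scaled with TMM factors, as mean ± SD, and log2 fold changes of sorted over crude are given ± SE.

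SynSURF sorted libraries held fewer counts, fewer genes and a higher share of Rn45s than crude ones. Crude libraries held 1035423 to 8897238 counts and 12236 to 14701 genes with a count. Of the sorted libraries, 9 held 76520 to 325117 counts, and replicate 1 held 1812759. The sorted libraries held 2588 to 6630 genes with a count. With every library thinned to 76520 counts, 7060 ± 396 genes were detected in crude and 3235 ± 506 in sorted libraries (n = 10 each, 10 of 10 sorted below the lowest crude, permutation test, adjusted p = 6e-05). The 10 most abundant genes took 7.22% ± 0.916 of counts in crude and 33.5% ± 17.4 in sorted libraries (n = 10 each, 10 of 10 sorted above the highest crude, permutation test, adjusted p = 6e-05). Rn45s, the 45S ribosomal RNA unit, whose counts do not separate precursor from mature ribosomal RNA, took 0.386% ± 0.220 in crude and 19.7% ± 20.8 in sorted libraries (n = 10 each, 10 of 10 above the highest crude, permutation test, adjusted p = 4.5e-05). This overlaps with the share of the 10 most abundant genes, since Rn45s was the most abundant gene in most sorted libraries. Its share was lowest in sorted replicate 2 at 0.805% (95% Wilson interval 0.767% to 0.845%) and highest in replicate 9 at 62.5% (62.1% to 62.8%). Ribosomal protein mRNAs took 2.29% ± 0.760 in crude and 3.01% ± 1.31 in sorted libraries (7 of 10 above the crude mean, permutation test, adjusted p = 0.194). Malat1, a nuclear RNA, took 0.00224% ± 0.000586 in crude and 0.00204% ± 0.00309 in sorted libraries (4 of 10 above the crude mean, permutation test, adjusted p = 0.922). Without sorted replicate 1, which alone held 0.0101%, the Malat1 share differed by -0.00109 percentage points (permutation test, adjusted p = 0.0429). In 4 sorted libraries Malat1 had a count of 0. At a floor of 3 counts this allowed shares of up to 0.000923% in replicate 4 and 0.00139% in replicate 10. In replicates 7 (0.00287%) and 9 (0.00351%) the allowed share lay above the crude mean, so their counts of 0 cannot show a lower share.

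**Figure D1:**
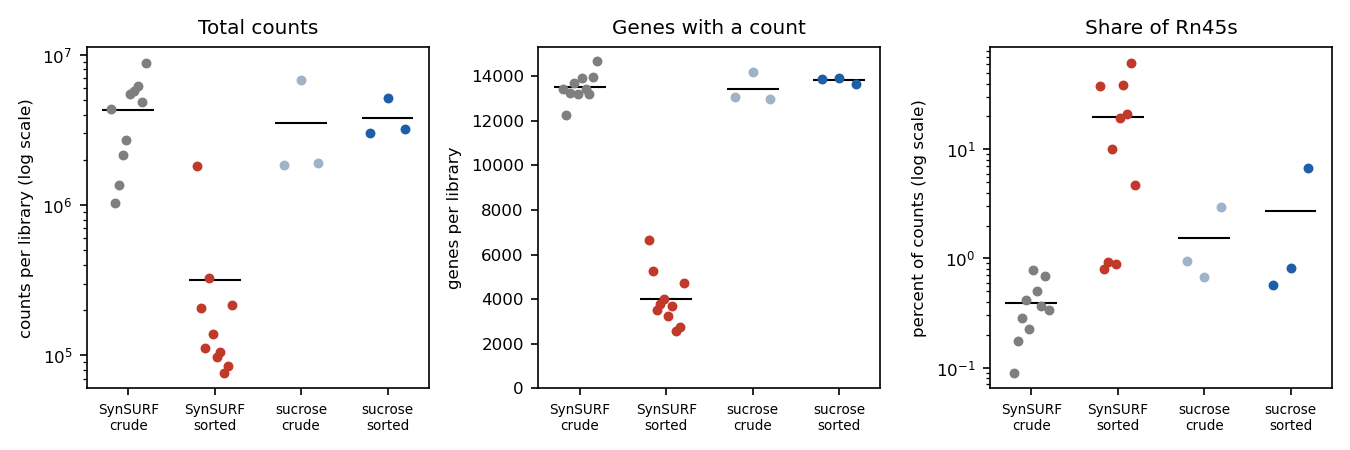
Total counts (log scale), genes with a count, and the percent of counts from Rn45s (log scale) for each library of the 4 groups, with the group mean as a line. SynSURF sorted libraries held 2588 to 6630 genes with a count, against 12236 to 14701 in SynSURF crude libraries.

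Across genes, the median Spearman correlation between SynSURF crude libraries was 0.826, between sorted libraries 0.365, and between crude and sorted libraries 0.40. Sorted replicate 4 had the lowest median correlation with the crude libraries, 0.291. Genes are not independent replicates, so these correlations describe the libraries only. In the sucrose set the same medians were 0.839, 0.865 and 0.872.

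The first comparison asked which RNAs were higher or lower in sorted than in crude SynSURF libraries. Mbp, which encodes myelin basic protein (chromosome 18, 82475146 to 82585637), rose from 2602 ± 908 to 38460 ± 21480 CPM (log2 fold change 3.89 ± 0.41, n = 10 each, edgeR adjusted p = 1.2e-06). Mobp, which encodes another basic protein of myelin (chromosome 9, 120149707 to 120181484), rose from 679 ± 164 to 11210 ± 4678 CPM (4.05 ± 0.40, edgeR adjusted p = 7.4e-07). Among astrocyte genes, of which 8 of 20 tested fell and 1 rose, lower genes included Aqp4, the water channel of astrocyte endfeet (167 ± 44.3 to 12.8 ± 21.3 CPM, -3.67 ± 0.85, edgeR adjusted p = 0.00164) and Gfap, an intermediate filament (66.3 to 8.98 CPM, log2 fold change -2.78 ± 0.70, edgeR adjusted p = 0.00346). The synaptic vesicle fusion protein Snap25 (chromosome 2, 136713453 to 136782428) rose from 1804 ± 356 to 4447 ± 2579 CPM in 9 of 10 sorted libraries (1.30 ± 0.42, edgeR adjusted p = 0.0195).

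Every sorted library lay above every crude library for 10 of 6598 genes tested, and below every crude library for 576, where chance gives 0.000541% of genes in each direction. With crude libraries thinned to the sorted totals, chosen after seeing the data, these numbers were 8 above and 11 below. The 10 were named after their values were seen. They were Mobp, Mbp, Rn45s, Trp53inp2, Pkp4, Fth1, Trak2, Bcas1, Map4 and Nudt3. Trp53inp2, which acts in autophagy, rose by 3.98 ± 0.54 (214 ± 86.0 to 3376 ± 2231 CPM) and Fth1, the ferritin heavy chain (chromosome 19, 9980598 to 9985098), by 3.18 ± 0.43 (2859 ± 1525 to 25830 ± 18270 CPM). Trak2, which links mitochondria to kinesin motors, rose by 2.97 ± 0.41, Bcas1, a gene of myelinating oligodendrocytes, by 3.80 ± 0.61, and the microtubule-binding Map4 by 2.82 ± 0.52. Among the 10 the edgeR adjusted p ran from 7.4e-07 for Mobp to 0.00083 for Nudt3.

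Over all genes, edgeR's quasi-likelihood test called 503 genes higher and 1458 lower after Benjamini-Hochberg adjustment, and 2631 had an unadjusted p under 0.05. The balance rested on the scaling. With library totals alone, chosen after seeing the data, 100 genes were higher and 2592 lower, and the median log2 fold change of all genes moved from -0.185 to -1.28, so each change is relative to that median. Mbp (2.84), Mobp (2.98), Fth1 (2.13), Trak2 (1.96), Aqp4 (-4.44) and Gfap (-3.86) passed the threshold under both scalings, while Snap25 (0.25, edgeR adjusted p = 0.653) did so only with TMM. Without any 1 crude library the number of higher genes was 307 to 358, and without any 1 sorted library 497 to 621. Without sorted replicates 1 and 4 (left out after seeing the data) 497 genes were higher and 2346 lower.

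**Figure D2:**
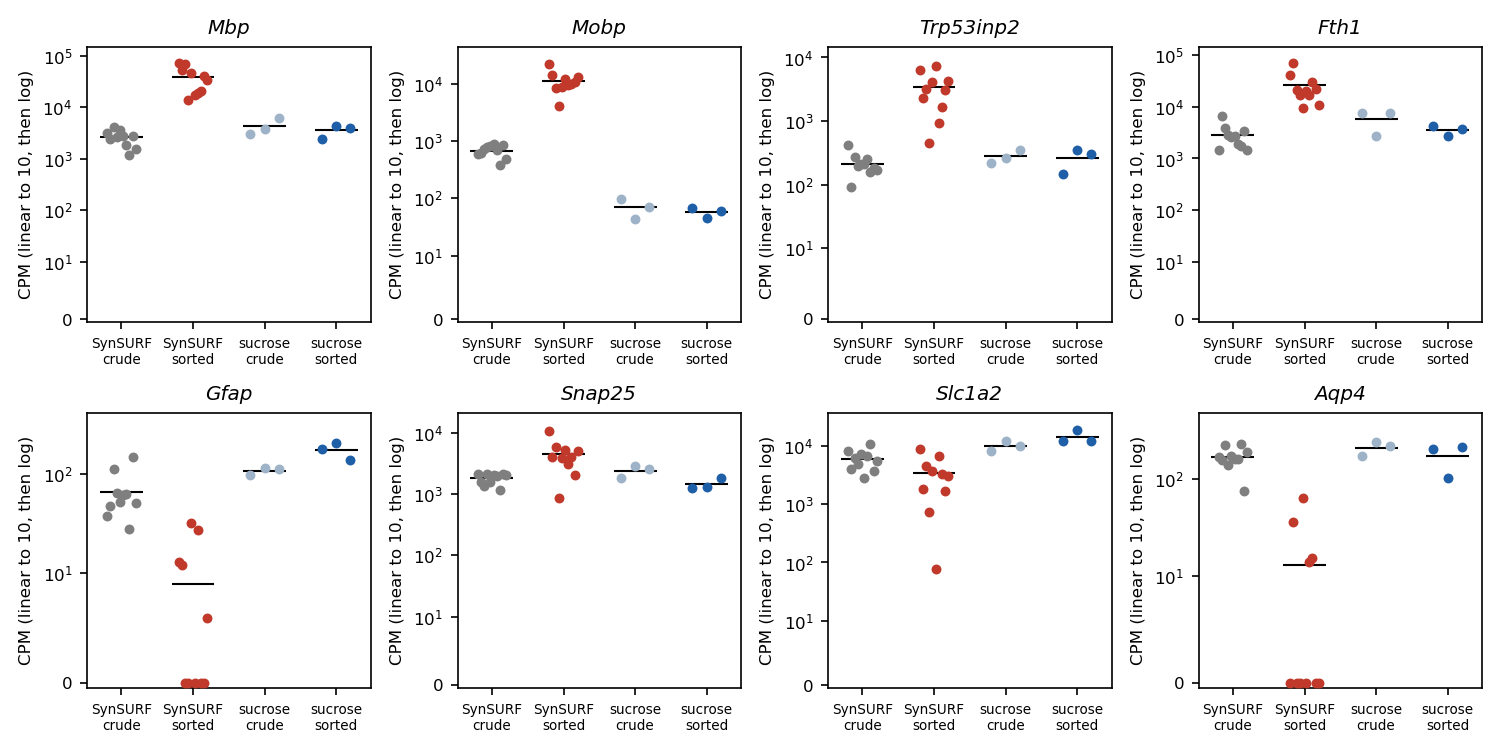
TMM-scaled CPM (linear up to 10, then log) of 8 genes in each library of the 4 groups, with the group mean as a line. Mbp, Mobp, Trp53inp2 and Fth1 lay above every SynSURF crude library in all 10 SynSURF sorted libraries, and Aqp4 lay below every crude library in all 10.

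The genes with the highest fitted fold changes came mostly from single libraries. Hnrnpm, a splicing factor, had a log2 fold change of 7.74 ± 1.67 (edgeR adjusted p = 8.44e-04), and sorted replicate 4 gave 96.8% of its sorted mean. Without that library it was 3.05 (edgeR adjusted p = 0.0137). Aph1a, a gamma-secretase subunit, went from 6.25 ± 1.53 to 3.17, Prrc2a from 6.21 ± 1.45 to 3.42 and Serf2 from 6.06 ± 1.26 to 3.46 when the same library was left out. Without sorted replicates 1 and 4, chosen after seeing the data, SynSURF Hnrnpm stood at -0.73, SynSURF Aph1a at -7.97, SynSURF Prrc2a at 0.54 and SynSURF Serf2 at 0.92, and with the replicate block they stood at 0.44, -1.13, 0.37 and 1.27. Aph1a had counts in no sorted library but replicates 1 and 4. Its 3.17 thus rests on replicate 1, and its -7.97 is a fitted value and no bound. Arl8a, a lysosomal small GTPase, had 6.67 ± 1.56 with 98.8% of its sorted mean in replicate 1, and 0.51 without it (edgeR adjusted p = 0.595). Rn45s stood at 7.06 ± 0.85 (edgeR adjusted p = 5.29e-06), and 10 of 10 sorted libraries lay above every crude library. Of the 503 higher genes, 332 took over 50% of their sorted mean from 1 library, which was replicate 4 for 149 and replicate 1 for 36.

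The genes with the lowest fitted fold changes had no count in any sorted library. With crude counts pooled and against a floor of 3 counts over the sorted group, Ptprr, a tyrosine phosphatase, was at least 108.5-fold lower than in crude libraries (234 ± 111 CPM), and the orphan receptor Gpr158 at least 85.6-fold lower (206 ± 106 CPM). Klhl42 was at least 56.9-fold, Unc79 at least 52.4-fold, the serine palmitoyltransferase subunit Sptlc1 at least 50.5-fold and the cannabinoid receptor Cnr1 at least 41.1-fold lower. For all 6 the edgeR adjusted p was at most 1.56e-05. Of the 1458 lower genes, 146 had no count in the sorted libraries and 774 had counts in at most 2 of them.

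The oligodendrocyte list passed the list test upward (camera adjusted p = 1.05e-04, and adjusted p = 0.0888 with an estimated correlation). Of 17 tested members 6 rose, 1 fell and 10 did not pass, and over the list alone 8 rose and 2 fell, adjusted over the list alone. The median log2 fold change was 1.10, 0.14 with library totals, and -0.75 with the replicate block. Besides Mbp and Mobp, Cryab, a small heat shock protein, rose by 1.68 ± 0.51 (452 ± 213 to 1448 ± 930 CPM, edgeR adjusted p = 0.0151), and Cnp, an enzyme of uncompacted myelin, by 1.85 ± 0.64 (372 ± 283 to 1345 ± 1299 CPM, edgeR adjusted p = 0.029), a call lost without any 1 of 4 libraries. With library totals Cryab (0.84) and Cnp (1.04) did not pass. Ugt8a, which makes a myelin lipid, fell by 2.69 on the log2 scale. Cryab and Cnp were named after their values were seen, and so were Syt1, Vamp2, Gria2, Lrrc7, Sparcl1, Slc1a3, Ctss, C1qc, Sv2b, Lingo1, Gad2 and Reln below.

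Synaptic genes, like all tested genes (1458 of 6598 lower, 503 higher), held more members that fell than rose. Of 27 presynaptic genes tested, 2 rose and 7 fell, the same counts when adjusted over the list alone (median -0.03, camera adjusted p = 0.82). Snap25 and Vamp2, both SNARE proteins, were the 2 that rose, Vamp2 by 2.48 ± 0.75 (192 ± 89.7 to 1073 ± 1665 CPM, edgeR adjusted p = 0.0144), and neither passed with library totals. Without sorted replicate 8 Vamp2 stood at 1.52 (edgeR adjusted p = 0.0779). Syt1, the calcium sensor of vesicle release, fell by 2.83 ± 0.66 on the log2 scale (2132 ± 621 to 301 ± 488 CPM, edgeR adjusted p = 0.00184). Syn1 had 0.46 ± 0.81 (edgeR adjusted p = 0.698). Of 25 postsynaptic genes, 0 rose and 9 fell (median -0.49, camera adjusted p = 0.273), and 2 rose and 10 fell adjusted over the list alone. Gria2, an AMPA receptor subunit, fell from 773 ± 140 to 91.0 ± 102 CPM (-3.08 ± 0.72, edgeR adjusted p = 0.00173), and the scaffold gene Lrrc7 from 521 ± 167 to 122 ± 211 CPM (-2.07 ± 0.72, edgeR adjusted p = 0.0301, and 0.0562 without crude replicate 1). Without sorted replicate 10 Lrrc7 stood at -3.21, and without replicate 6 Camk2a at -0.40. Camk2a (chromosome 18, 60925618 to 60988152) had 0.93 ± 0.80 (218 ± 104 and 414 ± 819 CPM, edgeR adjusted p = 0.40), the scaffold gene Dlg4 1.82 ± 0.74 (edgeR adjusted p = 0.0639, passed without sorted replicate 1, 2, 5, 6, 7 or 8, and 0.94 with adjusted p = 0.313 without replicate 4), and the immediate early gene Arc -0.18 ± 0.70 (edgeR adjusted p = 0.862). Without sorted replicate 2 Arc stood at -2.05 (edgeR adjusted p = 0.0327).

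Neuronal class markers and astrocyte and microglial markers, like all tested genes, held more falling than rising members, and none of these lists passed the list test. Of 11 glutamatergic genes 0 rose and 5 fell (median -1.31, camera adjusted p = 0.0775), with Sv2b at -3.52 ± 0.61 (704 ± 192 to 61.2 ± 48.0 CPM, edgeR adjusted p = 7.28e-05) and Lingo1 at -3.13 ± 0.86. Slc17a7, the vesicular glutamate transporter (chromosome 7, 45163949 to 45176142), had -1.31 ± 0.74 (58.5 ± 25.3 and 22.6 ± 28.5 CPM, edgeR adjusted p = 0.189), and -2.62 with library totals (edgeR adjusted p = 0.00711). Of 8 GABAergic genes 1 rose and 4 fell (median -1.59, camera adjusted p = 0.305). Reln fell from 91.8 ± 50.5 to 0.966 ± 2.11 CPM (-5.77 ± 0.79, edgeR adjusted p = 1.04e-05) and Gad2, a GABA-synthesising enzyme, from 98.4 ± 40.0 to 9.89 ± 18.1 CPM (-3.33 ± 0.85, edgeR adjusted p = 0.00383), while its paralog Gad1 had 0.43 ± 0.93 (edgeR adjusted p = 0.754), and -0.91 without sorted replicate 4. Of 20 astrocyte genes 1 rose and 8 fell (median -1.26, camera adjusted p = 0.273), and 2 rose and 8 fell adjusted over the list alone. Sparcl1, a secreted matrix protein, fell from 2401 ± 975 to 216 ± 126 CPM (-3.48 ± 0.50, edgeR adjusted p = 1.39e-05) and the glutamate transporter Slc1a3 by 1.77 ± 0.65, a call lost without any 1 of 11 libraries. Slc1a2, the main glial glutamate transporter (chromosome 2, 102658659 to 102790784), had -0.81 ± 0.52 (6097 ± 2435 and 3472 ± 2719 CPM, edgeR adjusted p = 0.249), and -1.87 with library totals (edgeR adjusted p = 0.00368). Of 11 microglial genes 0 rose and 5 fell (median -1.12, camera adjusted p = 0.168), with Ctss at -2.38 ± 0.88 and C1qc at -2.33 ± 0.81, calls lost without any 1 of 9 and of 2 libraries. Cx3cr1 and Cldn5 did not pass the expression filter.

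Lists of translation and RNA processing genes passed the list test upward. Of 76 ribosomal protein genes 13 rose and 1 fell (5 and 0 adjusted over the list alone), with a median of 0.90 and camera adjusted p = 8.91e-12 (adjusted p = 0.0888 with an estimated correlation). Rpl27 rose by 1.61 ± 0.42 (3054 ± 1099 to 9309 ± 5468 CPM, edgeR adjusted p = 0.00495) and Rplp1 by 1.37 ± 0.47 (edgeR adjusted p = 0.0303), which lost its call without any 1 of 5 libraries. Rps3 had 2.84 ± 0.87 (edgeR adjusted p = 0.0151), and 2.05 without sorted replicate 5 (edgeR adjusted p = 0.0519). Of 29 translation factors 10 rose and 2 fell (median 1.10, camera adjusted p = 1.82e-04, and adjusted p = 0.128 with an estimated correlation), and 13 and 3 adjusted over the list alone. Of 27 splicing and nuclear RNA-binding genes 16 rose and 0 fell (median 2.27, camera adjusted p = 2.3e-06, and adjusted p = 0.256 with an estimated correlation), and 18 rose and 1 fell adjusted over the list alone. Sorted replicate 4 held 70.9% to 94.3% of the sorted mean of Eif4g2, Pabpc1, Eif5a, Hnrnph1, Ddx5 and Hnrnpd, the most abundant members of these lists. With it left out, Eif4g2 moved from 3.80 ± 0.92 to 2.14 and Eif5a from 5.00 ± 1.08 to 3.18, while Pabpc1 (5.49 to 2.98), Hnrnph1 (5.92 to 2.01), Ddx5 (3.64 to 1.17) and Hnrnpd (5.83 to 1.84) no longer passed. The number of splicing genes that rose then went from 16 to 2 and their median to 0.83, and the number of translation factors from 10 to 8 with a median of 0.62. Without sorted replicates 1 and 4 the splicing median was 0.20 (camera adjusted p = 0.057).

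The cytoskeleton list also passed (4 of 25 rose, 7 without sorted replicate 4, 0 fell, 2 rose adjusted over the list alone, median 0.74, camera adjusted p = 6e-05, and adjusted p = 0.0888 with an estimated correlation). Its most abundant members were Tuba1b (4.26 ± 1.10, and 0.84 without sorted replicate 4), Kif5b (1.01 ± 0.46, edgeR adjusted p = 0.0996, and 0.0487 without sorted replicate 8) and Actg1 (0.09 ± 0.48). Nuclear-encoded oxidative phosphorylation genes passed with a median of 0.14 (6 of 53 rose, 4 fell, 1 rose adjusted over the list alone, camera adjusted p = 0.00269, and adjusted p = 0.253 with an estimated correlation). Cox4i1, a subunit of complex IV, rose by 2.70 ± 0.65 (edgeR adjusted p = 0.00249), whereas the ATP synthase genes Atp5a1 (0.37 ± 0.56, and -0.05 without sorted replicate 7) and Atp5c1 (0.92 ± 0.78, and 0.21 without replicate 4) did not pass, and stood at -0.63 and -0.39 with library totals. Glycolysis genes passed (3 of 16 rose and 2 fell, also adjusted over the list alone, median 0.71, camera adjusted p = 0.0193, and adjusted p = 0.17 with an estimated correlation). Gapdh rose by 1.25 ± 0.48 (edgeR adjusted p = 0.0497, lost without any 1 of 15 libraries), Ldhb had 2.16 ± 0.76 (0.86 without sorted replicate 3, and not passed without any 1 of 7 libraries) and Tpi1 4.00 ± 1.38, with 97.4% of its sorted mean from replicate 2 and -1.11 without it. Dendritic mRNAs passed (2 of 18 rose, 1 fell, 0 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.0325, and adjusted p = 0.204 with an estimated correlation), with Kif5a at 1.42 ± 0.51 (0.86 without sorted replicate 1, and not passed without any 1 of 11 libraries) and Ppp3ca at -0.08 ± 0.45. Without sorted replicate 2 the glycolysis and dendritic lists did not pass (camera adjusted p = 0.0526 for each), and the dendritic median was -0.04 without replicate 4 and -0.08 without replicate 6. With library totals alone the medians of ribosomal protein (-0.19), cytoskeleton (-0.23), oxidative phosphorylation (-0.81), glycolysis (-0.22) and dendritic (-0.80) genes lay below 0, and those of splicing (1.11) and translation factor (0.18) genes above 0. Of these lists glycolysis (camera adjusted p = 0.0505) and dendritic mRNAs (camera adjusted p = 0.105) then did not pass, and Rpl27 (0.64), Rplp1 (0.40), Rps3, Gapdh, Ldhb, Tpi1, Ddx5 and Kif5a lost their calls.

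The remaining lists did not pass the list test. These were oligodendrocyte precursors (0 of 6 rose, 1 fell, median 0.37, camera adjusted p = 0.99), endothelial (0 of 3 rose, 1 fell, -1.03, 0.325), choroid plexus and ependyma (0 of 3 rose, 1 fell, -2.32, 0.101), erythroid (0 of 3 rose or fell, -0.42, 0.532), nuclear-retained RNAs (0 of 5 rose or fell, 0.80, 0.273), immediate early genes (0 of 9 rose, 1 fell, -0.18, 0.974) and chaperones (0 of 17 rose or fell, 0.30, 0.168). Malat1 had 1.63 ± 0.77 (edgeR adjusted p = 0.114), and -0.40 without sorted replicate 1. Adjusted over the list alone, 3 choroid plexus genes fell, 1 erythroid gene rose and 1 fell, and the other counts were the same. The precursor list had a mean of -0.26, against its median of 0.37, and the erythroid list had a positive camera direction. Without sorted replicate 4 the erythroid median was 0.41 and 2 members rose. Mural genes had too few tested members.

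**Figure D3:**
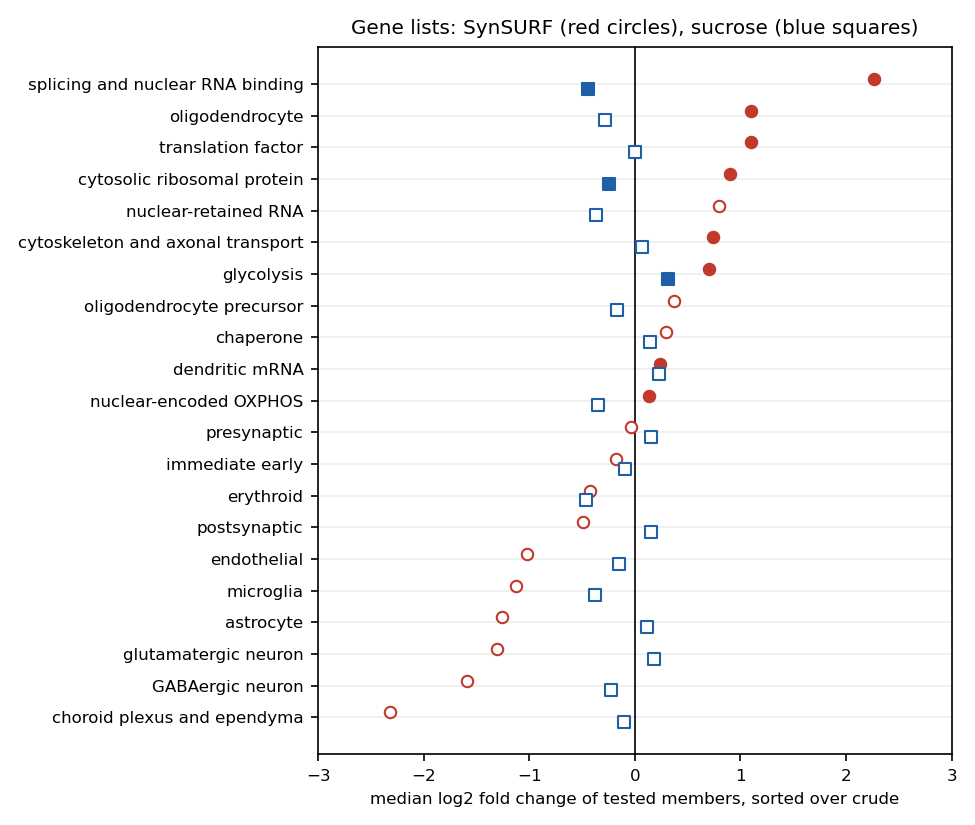
Median log2 fold change of the tested members of each gene list, sorted over crude, for SynSURF (red circles) and sucrose (blue squares), filled where the list's camera adjusted p passed the threshold. SynSURF medians ran from -2.32 (choroid plexus and ependyma) to 2.27 (splicing), and with library totals alone the ribosomal protein, cytoskeleton, oxidative phosphorylation, glycolysis, dendritic, oligodendrocyte precursor, nuclear-retained and chaperone medians changed sign.

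The second comparison asked the same of the sucrose gradient preparation, where no single gene passed the threshold. Mbp stood at 4359 ± 1712 CPM in crude and 3563 ± 980 in sorted libraries (log2 fold change -0.29 ± 0.39, n = 3 each, edgeR adjusted p = 0.999). Snap25 stood at 2397 ± 528 and 1461 ± 309 CPM (-0.72), Camk2a at 594 ± 337 and 965 ± 288 CPM (0.70), Slc1a2 at 10280 ± 1967 and 14490 ± 3684 CPM (0.50) and Gfap at 108 ± 9.74 and 174 ± 33.9 CPM (0.69), each with an edgeR adjusted p of 0.999. The rest of the panel ran from Malat1 at -0.57 to Dlg4 at 0.77, with Aqp4 at -0.28, Slc17a7 at 0.36, Gad1 at 0.35, Syn1 at 0.08, Arc at -0.31, Rplp1 at -0.28 and Cx3cr1 at -0.02. Leaving out 1 library moved these values widely, Dlg4 from 0.18 to 2.41, Slc17a7 from -0.24 to 1.23, Malat1 from -1.53 to 0.16 and Cx3cr1 from -0.55 to 0.76, and also turned the sign of Mbp, Syn1 and Arc. Cldn5 did not pass the expression filter.

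Of 10589 genes edgeR called 0 higher and 0 lower, with 324 at an unadjusted p under 0.05 (209 higher, 115 lower) and a smallest adjusted p of 0.246. Voom called 0, and the DESeq2 Wald test called 1 higher (Pcdhgc4, adjusted p = 0.0046) and 2 lower (Pcdhga11, adjusted p = 2.01e-07, and 2610028E06Rik, adjusted p = 0.0162), named after their values were seen. Pcdhga11 and Pcdhgc4 are protocadherin genes that share exons, so their counts depend on how the authors' counting split reads. Pcdhga11 had no count in sorted libraries and stood at 33.8 ± 25.6 CPM in crude libraries, at least 86.0-fold higher against a floor of 3 counts over the sorted group. The 3 sorted libraries lay above all crude libraries for 484 genes and below them for 407, where chance gives 5% of genes in each direction. With replicate number as a block, 0 genes were higher and 1 lower (Pcdhga11, edgeR adjusted p = 0.0354), with 939 at an unadjusted p under 0.05.

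Some sucrose gene lists passed the camera test with small shifts. Ribosomal protein genes were lower (14 of 79 members with a positive log2 fold change, median -0.24, camera adjusted p = 0.00832), with Rpl27 at -0.33, Rplp1 at -0.28 and Rps3a1 at -0.23. Splicing genes were lower (6 of 29 positive, median -0.45, camera adjusted p = 0.00832), with Matr3 at -0.62, Ddx5 at -0.50 and Sf3b1 at 0.13. Glycolysis genes were higher (12 of 16 positive, median 0.32, camera adjusted p = 0.0173), with Tpi1 at 0.91, Gapdh at 0.30 and Aldoc at 0.13. With an estimated correlation no list passed, and the smallest adjusted p was 0.776. With the replicate block, postsynaptic (median 0.22, camera adjusted p = 0.0368), dendritic (0.24, adjusted p = 0.0493) and astrocyte (0.18, adjusted p = 0.0437) genes were also higher, and oligodendrocyte (-0.25, adjusted p = 0.0437) and microglial (-0.27, adjusted p = 0.0437) genes also lower. In no list did a single member pass, over all genes or adjusted over the list alone.

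The other sucrose lists did not pass in either fit. Without the block their camera adjusted p ran from 0.155 for oxidative phosphorylation (median -0.35) to 0.968 for GABAergic neurons (-0.22). Between these lay presynaptic (0.15), glutamatergic (0.18), oligodendrocyte precursor (-0.17), endothelial (-0.15), mural (-0.25), choroid plexus (-0.10), erythroid (-0.46), translation factor (0.01), nuclear-retained (-0.36), immediate early (-0.09), chaperone (0.14) and cytoskeleton (0.07) medians. The glutamatergic list had a mean of -0.05 and a negative camera direction, and the GABAergic list a positive one, each against the sign of its median. The counts of the sucrose libraries ran from 1844679 to 6793374, with 12960 to 14204 genes with a count, and ribosomal protein mRNAs took 2.99% ± 0.732 of crude and 2.56% ± 0.438 of sorted counts (exact permutation test, p = 0.6, smallest possible p = 0.1). Rn45s took 1.53% ± 1.24 of crude and 2.70% ± 3.47 of sorted counts (exact permutation test, p = 0.9), the 10 most abundant genes 7.56% ± 1.10 and 8.67% ± 3.15 (p = 0.8), and Malat1 0.00261% ± 0.00186 and 0.00176% ± 0.00147 (p = 0.5). These tests did not use the pairing. The Malat1 share was lower in the sorted library of each pair, at 0.000861% against 0.00103%, 0.000962% against 0.00215% and 0.00345% against 0.00466%. At equal depth 12990 ± 73.6 genes were detected in crude and 13150 ± 205 in sorted libraries (exact permutation test, p = 0.3).

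In the authors' deposited table of their own sucrose comparison, 312 of 24444 genes had a PPEE under 0.05, of which 175 had a fold above 1 and 137 a fold below 1. In the authors' deposited table the folds were 0.808 for Mbp, 1.61 for Camk2a and 1.39 for Slc1a2. Across 10589 genes, the Spearman correlation of the folds in the authors' deposited table with the log2 fold changes here was 0.999.

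The third comparison tested whether the effect of sorting differed between the preparations. For Mbp and Mobp the effect was higher in SynSURF than in sucrose libraries. In the 4-group fit, crude Mobp stood at 829 ± 216 CPM in SynSURF and 57.2 ± 21.7 in sucrose libraries, and crude Mbp at 3155 ± 1053 and 3515 ± 1303. Why crude Mobp differed was not tested, so its result may not rest on sorting alone. The difference of the log2 fold changes was 3.75 ± 0.70 for Mbp (edgeR adjusted p = 7.4e-04) and 3.96 ± 0.71 for Mobp (edgeR adjusted p = 6.94e-04). The same difference was 4.32 ± 1.13 for Bcas1, 3.62 ± 0.95 for Trp53inp2, 3.54 ± 0.79 for Fth1, 3.47 ± 0.88 for Pkp4 and 2.96 ± 0.73 for Trak2, and 8 of the 10 genes that were separated in SynSURF passed. Map4 (2.48 ± 0.92, edgeR adjusted p = 0.0579) and Nudt3 (2.39 ± 1.19, edgeR adjusted p = 0.172) did not. Lower in SynSURF than in sucrose were Gfap (-3.87 ± 1.19, edgeR adjusted p = 0.0233), Sparcl1 (-3.83 ± 0.83, edgeR adjusted p = 0.00203), Sv2b (-4.09 ± 1.08, edgeR adjusted p = 0.00879), Reln (-5.64 ± 1.22, edgeR adjusted p = 0.00203) and Syt1 (-3.52 ± 1.21, edgeR adjusted p = 0.041). Of other genes lower within SynSURF, Aqp4 (edgeR adjusted p = 0.0624), Lingo1 (0.0783), Gad2 (0.0857) and Gria2 (0.0988) did not pass. Neither did Lrrc7 (edgeR adjusted p = 0.132), Slc1a3 (0.248), Ctss (0.335) or C1qc (0.848). With the replicate block in both preparations Aqp4, Lingo1, Gad2, Gria2 and Lrrc7 passed, though in simulated SynSURF data that block ran low. The difference did not pass for the oligodendrocyte genes Cryab (1.54 ± 0.99, edgeR adjusted p = 0.31) and Cnp (1.23 ± 1.22, edgeR adjusted p = 0.549). The difference for Snap25 was 1.61 ± 0.75 (edgeR adjusted p = 0.141) and for Slc1a2 -1.70 ± 0.97 (edgeR adjusted p = 0.239).

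Of 10713 genes, edgeR called 32 higher and 1853 lower in SynSURF than in sucrose (3295 at an unadjusted p under 0.05, median difference -1.17). In simulated data the same test recovered fewer raised than lowered genes, so how much of this imbalance comes from the test cannot be told. With the replicate block in both preparations edgeR called 10 higher and 2708 lower, and with a block of the sucrose pairs alone, chosen after seeing the data, 14 higher and 1714 lower. The highest differences were those of Lsm12 (8.67 ± 3.03), Hnrnpa2b1 (8.54 ± 2.92), Hnrnph3 (8.38 ± 2.56), Btbd7 (8.15 ± 2.52), Rn45s (5.78 ± 1.57) and Foxc1 (5.42 ± 1.78). The calls of Lsm12 and Hnrnpa2b1 were lost without any 1 of the 6 sucrose libraries, and those of Hnrnph3 and Btbd7 without any 1 of 3. With the block of the sucrose pairs the edgeR adjusted p was 0.0599 for Lsm12, 0.0538 for Hnrnpa2b1, 0.0625 for Foxc1 and 0.0521 for Syt1, so these calls were lost. With the block in both preparations Syt1 passed, and the edgeR adjusted p was 0.0678 for Hnrnph3, 0.0659 for Btbd7, 0.151 for Lsm12, 0.364 for Hnrnpa2b1 and 0.451 for Foxc1. Mbp, Mobp and Rn45s passed with either block. Without SynSURF sorted replicate 4, Hnrnpa2b1 went to 4.85, Hnrnph3 to 4.90 and Foxc1 to 0.51, Lsm12 was not tested, and Rn45s kept its call without any 1 of the libraries left out (the 6 sucrose libraries and SynSURF sorted replicate 4). The genes with the lowest differences, Ptprr, Gpr158, Lrrc47, Klhl42, Unc79 and Slc1a4, had no count in SynSURF sorted libraries, so their fitted values are no bound, and each had an edgeR adjusted p of at most 7.36e-04. On the CPM scale of this fit, whose TMM factors were set over all 4 groups, Ptprr stood at 286 ± 137 in SynSURF crude (234 ± 111 in the SynSURF fit), 129 ± 43.5 in sucrose crude and 189 ± 67.6 in sucrose sorted libraries. Of the 1853 lower genes, 806 were tested within SynSURF, of which 802 were also called lower there. Of the 32 higher genes, 10 were also called higher within SynSURF. The count of higher genes was 16 without sucrose sorted replicate 1, 18 without replicate 2 and 16 without replicate 3.

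Among 6280 genes tested in both preparations, SynSURF had 482 higher and 1386 lower calls by edgeR and sucrose 0, so the overlap of calls could not be tested. Of the 482 higher SynSURF genes 37.6% had a positive sucrose log2 fold change, against 44.9% of all genes tested in both, and of the 1386 lower genes 49.3% did. The Spearman correlation of the fold changes across genes was -0.066, and genes are not independent replicates.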

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

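The split counts below were set before the data were examined, and the tests of whole oligodendrocytes, single libraries, scaling, depth, transcript length and spread were chosen after the results were seen.

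Mbp and Mobp rose in SynSURF sorted libraries and not detectably in sucrose sorted libraries, and the differences of the log2 fold changes, 3.75 and 3.96, passed edgeR's test of the difference. Crude Mobp itself stood at 829 CPM in SynSURF and 57.2 CPM in sucrose libraries in that fit, a gap whose cause was not tested. Whole oligodendrocytes among the sorted particles would raise the other oligodendrocyte transcripts by about as much. The 75th percentile of the log2 fold changes of the other 15 tested members was 1.77 (median 0.82), below the value of Mbp less 2 SE (3.07). Of these members 4 were called higher and 1 lower (Ugt8a, which fell by 2.69 on the log2 scale). Bcas1, an oligodendrocyte gene outside that list, rose by 3.80. Most of these members thus rose less than Mbp. The comparison cannot exclude whole oligodendrocytes, since it left out the SE of the other members and singled out Mbp and Mobp for their high values. The lowest value of either gene without any 1 sorted library was 3.72 (edgeR adjusted p at most 4.64e-06), and the lower of both with library totals alone was 2.84 (edgeR adjusted p at most 2.68e-06), which argues against a single library and against the scaling. With genes divided into 5 groups by transcript length, the highest 75th percentile of the log2 fold changes in any group was 1.31. Mbp and Mobp were singled out for their high values, so they would lie above such a percentile in any case. Transcript length therefore stays open for them. A candidate explanation is RNA of myelin fragments or oligodendrocyte processes among the sorted particles, a hypothesis not tested here, and unequal amplification also stays open for this pair.

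More genes were lower than higher in SynSURF sorted libraries, 1458 against 503. With crude libraries thinned to the sorted totals and the same 6598 genes fitted, 578 were lower and 203 higher by edgeR, but those genes were chosen at full crude depth, and with the default filter on the thinned libraries, which kept 1236 genes, 29 were lower and 69 higher, so depth stays open. Among the fifth of genes with the shortest transcripts 159 were lower and 160 higher, and among the fifth with the longest 377 were lower and 77 higher, so an effect of transcript length may account for the excess. Of genes simulated with no change and each group's own spread, 256 were called lower (4%) and 2 higher, against 22.1% of tested genes called lower, so the wider spread between sorted libraries could account for part of it, and how large a part cannot be told from these libraries. A difference between sorted and crude particles themselves also stays open, and so do their unlike buffer and particle number. The excess was larger with library totals alone (2592 against 100).

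Of 100 splits of the 20 SynSURF libraries, 1 (the real one) reached 503 higher genes, where the highest of the others, in its larger direction, was 70, and 1 of 100 reached 1458 lower genes (highest other 70). No random division drawn from these libraries thus gave either count. Every other split mixes crude libraries with sorted ones of mostly lower depth, so these shares cannot separate sorting from the gap in depth. For the number of called lists the margin was small. The real split called 8, reached in 1 of 100, and 4 other splits called 7 (highest other 7). With an estimated correlation 0 of the 8 lists passed, and without sorted replicate 2 the dendritic and glycolysis lists did not pass. The 6 sucrose libraries allow 10 splits, too few for a share under 0.05. The real split called 0 genes, a number reached in 10 of 10 splits (highest other 1), and 3 lists, a number reached in 5 of 10 (highest other 5). Among the other 3 splits that part every same-numbered pair the most lists was 3 and the most genes 0, and the 6 splits that part fewer pairs gave 1 to 5 lists. For the difference between preparations, 2 of 100 splits reached 32 genes, the number higher in the real one, and 1 of 100 reached 1853, the number lower (highest other 1750 in either direction). By the bound written before the test both shares would exclude chance, and that reading was dropped only after the counts were seen, because the design fixes the outcome. Splits that moved SynSURF libraries between groups called at most 4 genes in either direction, so these shares were set by the gap between SynSURF crude and sorted libraries, a structure of the samples. The 1 other split that kept the SynSURF groups called 40 genes higher and 1750 lower, and so few such splits cannot exclude chance among the sucrose libraries.

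In 45 of 142 groups of 10 libraries tested, 1 library stood apart from the others, where chance gives about 1 in 20. The genes tested include those chosen for the highest fold changes, so this comparison with chance decides nothing. SynSURF sorted replicate 1 held 1812759 counts, against at most 325117 in the others, and a Malat1 share of 0.0101%. Of 30 such gene values in sorted libraries 14 were in replicate 4, 5 in replicate 1 and 3 in replicate 2. Replicate 4 was highest in Hnrnpm (17220 CPM), Hnrnph1 (50990), Hnrnpd (35430), Ddx5 (31150), Eif4g2 (82670), Pabpc1 (63300), Eif5a (37040), Tuba1b (51510), Serf2 (29520), Prrc2a (10620), Aph1a (6473), Atp5c1 (2863), Gad1 (1485) and Dlg4 (167.5). Replicate 1 was highest in Arl8a (30230 CPM), Snap25 (10440), Kif5a (8472), Bcas1 (3619) and Malat1 (338.4), and replicate 2 in Fth1 (71270 CPM), Tpi1 (55010) and Arc (89.47). Ldhb was highest in replicate 3 (7090 CPM), Camk2a (2642) and Syt1 (1656) in replicate 6, Rplp1 in replicate 7 (9023), Vamp2 in replicate 8 (5626), C1qc in replicate 9 (95.67), and Nudt3 (10490) and Lrrc7 (712) in replicate 10. Among SynSURF crude libraries, 13 gene values stood apart. Replicate 1 was highest in Cnp (1163 CPM), Lrrc7 (906.3), Map4 (481.8) and Vamp2 (402.9). Replicate 2 was highest in Fth1 (6551 CPM), Cox4i1 (3513), Ctss (399.2) and Reln (223), and lowest in Nudt3 (100.1). Klhl42 (206.1 CPM) and Hnrnph1 (159.6) were highest in replicate 8, and Tpi1 (813.8) and Arl8a (64.25) in replicate 9.

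The effect of sorting differed between preparations for 32 genes higher and 1853 lower in SynSURF, by edgeR's test of the difference. In simulated data that test recovered at most 7.7% of raised genes at any fold, and 17.6% to 58.3% of lowered ones. It called 59 of 10513 unchanged genes lower and 0 higher. The imbalance of the calls therefore cannot be read as one of the samples. Of the lower genes, 806 were tested within SynSURF and 802 were also called lower there. Depth and transcript length thus stay open for them. Besides Mbp and Mobp, the difference of the log2 fold changes was above 0 for Lsm12 (8.67), Hnrnpa2b1 (8.54), Hnrnph3 (8.38), Btbd7 (8.15), Rn45s (5.78), Foxc1 (5.42), Bcas1 (4.32), Trp53inp2 (3.62), Fth1 (3.54), Pkp4 (3.47) and Trak2 (2.96). With a block of the sucrose pairs alone, the calls of Lsm12, Hnrnpa2b1, Foxc1 and Syt1 were lost (edgeR adjusted p = 0.0599, 0.0538, 0.0625 and 0.0521), and without SynSURF sorted replicate 4 Foxc1 stood at 0.51. Below 0 were Reln (-5.64), Sv2b (-4.09), Gfap (-3.87), Sparcl1 (-3.83) and Syt1 (-3.52). Ptprr (-13.26), Gpr158 (-12.42), Lrrc47 (-12.40), Klhl42 (-11.94), Unc79 (-11.73), Slc1a4 (-11.73), Sptlc1 (-11.64) and Cnr1 (-10.97) had no count in SynSURF sorted libraries, so these fitted values are no bounds.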

How the results depend on the processing

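Library totals, leaving out sorted replicate 4 or replicates 1 and 4, thinning of crude libraries, removal of Rn45s and the block of the sucrose pairs alone were chosen after the results were seen. For each value below that moved or turned, the cause was not tested unless stated. The SynSURF counts of 503 higher and 1458 lower genes became 77 and 2610 with voom, 37 and 2640 with the replicate block, 100 and 2592 with library totals, 816 and 3601 with no filter, 675 and 3330 with the DESeq2 Wald test, and 497 and 2346 without sorted replicates 1 and 4. In the simulated SynSURF data voom called 2325 and the block 1011 of 6398 unchanged genes lower, against 256 by the main test, and their fitted log2 fold changes of genes raised 8-fold had medians of 0.59 and 0.51, so in simulation both ran low. With thinned crude libraries they were 69 and 29, where the filter left 1236 genes. Leaving out 1 library gave 307 to 621 higher and 1247 to 2039 lower genes. Of the 503 higher genes, 269 were called higher by DESeq2, 100 with library totals, 76 by voom and 36 with the block, and of the 1458 lower genes 1451, 1458, 1232 and 1442. A minimum log2 fold change of 1 removed no call. Of 68 named SynSURF genes (53 called), 34 kept their side of the threshold under every alternative, with no sign change where either fit called them. Under some alternatives 27 lost the call and 6 gained one without a sign change, and 9 changed sign with a call in either fit. Sign changes without a call in either fit, such as that of Camk2a without sorted replicate 6, were not counted. Negative log2 fold changes were given by voom for SynSURF Pabpc1 (-2.04), SynSURF Ddx5 (-1.16), SynSURF Tpi1 (-2.40), SynSURF Tuba1b (-0.35) and SynSURF Gad1 (-2.40), and by DESeq2 for Tpi1 (-0.98). The replicate block gave them for SynSURF Arl8a (-0.046), SynSURF Aph1a (-1.13), Pabpc1 (-2.16), Ddx5 (-1.12), Tpi1 (-2.64) and Gad1 (-2.50). Without sorted replicates 1 and 4 they were SynSURF Hnrnpm (-0.73), Aph1a (-7.97), Pabpc1 (-1.50), SynSURF Hnrnph1 (-0.40) and Ddx5 (-0.92). Aph1a then had no count in any sorted library, so its value is no bound. Leaving out 1 library gave -1.11 (without sorted replicate 2) to 4.25 for Tpi1. The difference in Malat1 share ran from -0.00109 (without sorted replicate 1) to 3.37e-05 percentage points. SynSURF numbers did not meet the rule for pairing, since only 2 of 10 same-numbered correlations were over 0.1 (0.056 to 0.186). Still, 8 of 10 crude and 8 of 10 sorted libraries correlated best with their own number. A pairing of the SynSURF libraries thus stays open, and the main test does not use it.

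The 8 SynSURF lists higher became 0 with an estimated correlation, 0 higher and 11 lower with fry, which does not compare a list with other genes, and 2 of 12 with thinned crude libraries. With the replicate block the same 8 passed the camera test upward. The medians of oligodendrocyte (-0.75), dendritic (-0.74), oxidative phosphorylation (-0.69), translation factor (-0.38), glycolysis (-0.31) and splicing (-0.03) genes were then below 0. Those of ribosomal protein (0.29) and cytoskeleton (0.42) genes stayed above 0, and in simulation that block ran low. By fry the direction turned negative for lists with medians of 0.24 (dendritic), 0.37 (oligodendrocyte precursor), 0.14 (oxidative phosphorylation), 0.71 (glycolysis) and 0.30 (chaperone). In sucrose, the 0 called genes became 1 higher and 2 lower with DESeq2, 1 lower with no filter, 1 lower with the replicate block, and 0 to 1 lower without 1 library. The 1 higher and 2 lower sucrose lists became 0 and 0 with an estimated correlation, 0 and 0 with fry, and 4 and 4 with the block, which changed no other sucrose call. For the difference between preparations the 32 higher genes became 162 with voom, 19 with a minimum of 5 CPM, 10 with the block, 14 with a block of the sucrose pairs alone, 242 by the Wald z of separate DESeq2 fits, and 16 to 35 without 1 library. The 23 named sucrose genes stayed without a call under every alternative run. Leaving out libraries under the planned count minimum was not run in SynSURF, where 1 sorted library would have stayed. The sorted totals of 76520 to 1812759 counts limit what a count of 0 can show.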

Other observations

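The tests of gene lists on the difference between preparations and of single libraries were chosen after the results were seen, while the transcript length test of the ribosomal protein list was set before.

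Gene lists also differed between the preparations in the 4-group fit. The splicing list had a median difference of the log2 fold changes of 2.30 (camera adjusted p = 9.47e-09, and adjusted p = 0.218 with an estimated correlation). Within SynSURF 1 library carried much of the splicing shift, whose median went from 2.27 to 0.83 without sorted replicate 4. The ribosomal protein list had 0.62 (camera adjusted p = 1.5e-10, and 0.206 as the adjusted p with an estimated correlation). Further lists higher in SynSURF were oligodendrocyte (0.27, camera adjusted p = 0.000676), translation factor (0.51, adjusted p = 0.00129), oxidative phosphorylation (0.01, adjusted p = 0.00174), cytoskeleton (0.27, adjusted p = 0.00264) and nuclear-retained (0.73, adjusted p = 0.0408) genes. The postsynaptic list was lower (-1.83, camera adjusted p = 0.0408). With an estimated correlation the adjusted p of these lists ran from 0.206 to 0.384, so none passed, and 14 other lists did not pass with the preset one. The median difference of all genes was -1.17.

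Among oligodendrocyte genes not named above, all chosen after their values were seen, Qdpr, which recycles a cofactor of amine synthesis, rose by 1.85 ± 0.61 (edgeR adjusted p = 0.023) and Fa2h, which hydroxylates myelin lipids, by 2.91 ± 1.08 (edgeR adjusted p = 0.0422) in SynSURF sorted libraries. Opalin (-1.75 ± 0.70, edgeR adjusted p = 0.0598) and Mog (-1.36 ± 0.67, edgeR adjusted p = 0.13), both myelin membrane proteins, did not pass.

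Ribosomal protein mRNAs were shifted up in SynSURF sorted libraries, with a median log2 fold change of 0.90, and -0.19 with library totals alone, so the direction rests on the scaling. The list's adjusted p was 0.0888 with an estimated correlation. Among 10000 random lists matched on transcript length and crude level the median was 0.55, 95% of lists lay between 0.21 and 0.93, and the ribosomal protein list stood at the 96.11 percentile, so its short transcripts may account for the shift. Leaving out any 1 sorted library gave a camera adjusted p of at most 2.77e-10, which argues against a single library. In the same comparison the splicing list, with sorted replicate 4 included, stood at the 100 percentile, translation factors at 99.82, oligodendrocyte genes at 98.5, cytoskeleton at 97.93, glycolysis at 81.4, dendritic mRNAs at 77.54 and oxidative phosphorylation at 9.71. Over all SynSURF genes the median log2 fold change ran from 0.41 in the fifth with the shortest transcripts to -0.74 in the fifth with the longest, and in sucrose from -0.14 to 0.01.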
